A study of Mus musculus with 30 samples.

How the data were processed

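RNA sequencing of 28 mouse libraries was analysed, 2 replicates for each of 14 groups, from a single deposited table with 31961 gene symbols and a column per library. The deposited values are TPM by label and by column sums of 920040 to 945265. These lie below the fixed total of TPM, so some quantified genes are not in the table. The submitters' processing notes name STAR 2.7.3a, RSEM 1.3.1, fastp and the mouse genome mm10. Read counts were not used here, so depth per library and the counting error it gives are unknown, and precision was taken from the spread between replicates. The 2 CUT&Tag samples were not used here. Gene positions came from the RefSeq table of GRCm38, which holds 31551 of the symbols and 15347 of the tested ones.

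Each column was matched to a sample by its name. The column of iTSC OC-Epi No2 carries the prefix CT in place of OC-Epi and was matched by its line number. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples. The groups, comparisons, gene lists, main settings and first alternatives were chosen before the data were examined.

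TPM values were transformed as log2(TPM + 1), and 15454 genes with at least 1 TPM in at least 2 libraries were tested. All 14 groups were fitted in a single linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on mean expression), with the group as the only factor. There were 19 comparisons: the Klf5 knockout against wild-type ESCs, iKlf5 against iEmpty in each of the 4 combinations of day and medium, 4 interactions of these, CHIR with LIF against LIF in iEmpty on each day, EpiSCs against ESCs, iKlf5 of day 5 in each medium against ESCs, each iTSC line against TSCs and against EpiSCs, and TSCs against EpiSCs. P-values were adjusted by the method of Benjamini and Hochberg over the tested genes of a comparison, and a gene was called at an adjusted p below 0.05. The median SE of a log2 fold change was 0.188, and 0.266 for an interaction.

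The fit was tested on simulated data with 200 changed genes and the replicate numbers of the study. In the knockout comparison 25.4% of changes of 0.5 (log2), 70.1% of changes of 1 and 93.9% of changes of 2 were recovered, and 5.97% of the calls were unchanged genes. In the interaction on day 2 the recovered shares were 1.49%, 34.3% and 86.4%.

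Gene lists were tested with camera, with the preset correlation between genes of 0.01 and again with the correlation estimated from the data, and p-values were adjusted over all 418 tests. With the preset 134 were called, 30 of these also with the estimate. The 22 lists were naive pluripotency, primed pluripotency, general pluripotency, trophoblast stem cell, differentiated trophoblast, extraembryonic endoderm, primitive streak and mesoderm, neural ectoderm, WNT targets, LIF and STAT3 targets, 2-cell-like genes, germline genes silenced by methylation, epithelial, mesenchymal, feeder fibroblast markers, KLF family, p53 targets, stress and immediate early, cholesterol synthesis, glycolysis, mitochondrially encoded, and X inactivation and Y-linked. Some genes are in more than 1 list. Members called are counted with p-values adjusted over all tested genes and, beside it, over the list alone.

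The genes named were Klf5, the 10 with the highest and the 10 with the lowest log2 fold change among those called, with groups that do not overlap in any library, a mean of at least 5 TPM in a group and no predicted gene name, and the 3 highest and 3 lowest members of each list. For interactions the ranking used the difference itself. Examples in the text were taken from these.

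The position of a library on an axis is its projection on the line between the means of both end groups, over the genes called between them, and each end library was also placed on an axis built without it. Overlaps of called genes were tested with a one-sided Fisher exact test against the tested genes.

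The alternatives chosen then were median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter on low values (24152 genes), a minimum absolute log2 fold change of 1, a block for the replicate number, a fit with only the libraries of the comparison, leaving out each library in turn, the estimated correlation for lists, leaving Klf5 out, and all tested genes for the axes. Alternatives chosen after seeing the data were leaving out genes of chromosome 14 or of chromosomes 6 and 11, a fit without both day 5 LIF iKlf5 libraries, libraries weighted by the spread of their group (arrayWeights), and a block that pairs replicate 1 with replicate 2 of the other group. With 2 libraries per group no regrouping of samples was counted, since 2 against 2 cannot give a share under 0.05. Transcript lengths were not used here.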

Results

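RNA was measured by bulk RNA sequencing in 28 mouse libraries, 2 for each of 14 groups, with 1 value per gene symbol as TPM (transcript amounts scaled to a fixed total per library). Wild-type embryonic stem cells (ESC), which hold naive pluripotency, and ESCs with a Klf5 knockout formed 2 groups. Wild-type epiblast stem cells (EpiSC), which hold primed pluripotency, and wild-type trophoblast stem cells (TSC), the stem cells of the placenta, formed another 2. In 8 groups a Klf5 construct (iKlf5) or an empty construct (iEmpty) was sampled on day 2 or day 5 in leukemia inhibitory factor (LIF) or in LIF with CHIR, an inhibitor of GSK3 that activates WNT signalling. The last 2 groups were induced TSC lines (iTSC), Epi2-1 No5 and OC-Epi No2, which the series text describes as Klf5-induced. The number of genes with at least 1 TPM ran from 11567 to 13127 per library. Library depth is unknown. TPM values are given throughout as the mean ± SD of n = 2 libraries and log2 fold changes as the estimate ± SE of the fit. A value beside a gene without a unit is its log2 fold change, or for an interaction its log2 difference. Every gene named as an example outside a list had groups that did not overlap in any library, except Klf5 and the genes named for an interaction.

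Klf5 encodes a zinc-finger transcription factor and lies on chromosome 14 from 99298691 to 99313412 in GRCm38 (gene ID 12224). Its level was 134 ± 14 TPM in wild-type ESCs, 4.83 ± 0.728 in EpiSCs and 89.8 ± 21.6 in TSCs. The iKlf5 groups stood at 889.9 ± 42.4 TPM on day 2 in LIF, 949.8 ± 119 on day 2 with CHIR, 503 ± 263 on day 5 in LIF and 382 ± 23.2 on day 5 with CHIR. The iEmpty groups in the same order stood at 26.2 ± 4.67, 6.51 ± 2.45, 3.33 ± 2.41 and 0.575 ± 0.0212 TPM. The iTSC lines stood at 93.1 ± 1.77 TPM for Epi2-1 No5 and 78.4 ± 10.5 for OC-Epi No2.

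**Figure D1:**
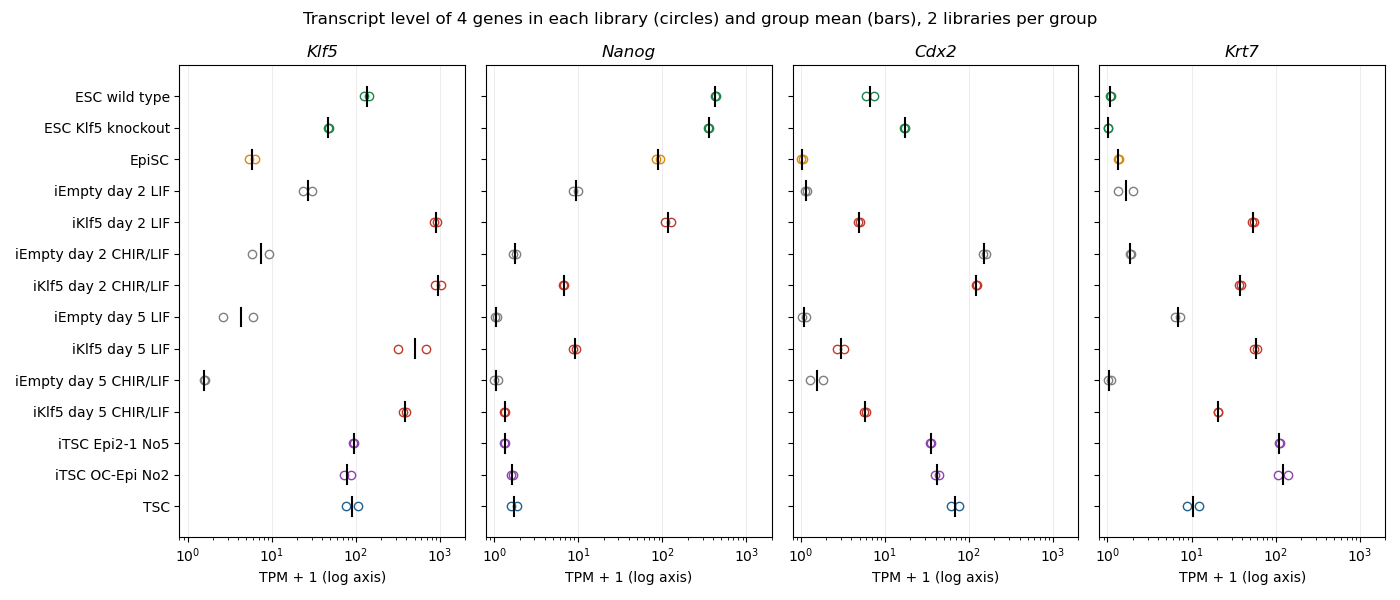
TPM + 1 on a log axis of Klf5, Nanog, Cdx2 and Krt7 in each of the 28 libraries (circles), with the group mean as a bar. Klf5 is at 317 TPM or more in every iKlf5 library, and Krt7 is higher in each iKlf5 group than in its iEmpty group.

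The replicates of day 5 iKlf5 in LIF stood further apart than those of any other group, with 4407 genes over 2-fold apart and r = 0.933 across genes, which are not independent. In the other 13 groups 41 to 574 genes were over 2-fold apart and r was 0.986 to 0.997. Ribosomal protein genes took 29.7% of the TPM in replicate 1 of that group and 15.1% in replicate 2, and mitochondrially encoded genes took 6.75% and 14.9%. The fit shares 1 estimate of spread per gene among all groups, so comparisons that use this group do not carry its own spread in full and the others carry part of it. The fits without both of its libraries and with weighted libraries were chosen after seeing the data.

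EpiSCs against ESCs gave the reference for the primed and the naive state. Dppa5a, Zfp42 and Esrrb, genes of naive ESCs, stood at 1566 ± 199.7, 213 ± 6.98 and 228 ± 4.49 TPM in ESCs and at 0.305 ± 0.106, 0.035 ± 0.0495 and 0.265 ± 0.0778 in EpiSCs (log2 fold change -10.23 ± 0.33, -7.69 ± 0.14 and -7.50 ± 0.12). Fgf5 was higher in EpiSCs by 6.80 ± 0.13 (log2) and Egr1, an immediate early gene, by 7.60 ± 0.46. In the list of naive pluripotency genes 0 of 18 were higher and 18 lower (0 and 18 adjusted over the list alone), with adjusted p = 8.2e-17 and 3.1e-05 with an estimated correlation. Among primed pluripotency genes 15 of 16 were higher and 0 lower (15 and 0 adjusted over the list alone), with adjusted p = 6.9e-09 and 0.16 with an estimated correlation. Germline genes silenced by DNA methylation, led by Rpl10l (-6.93) and Fkbp6 (-4.84), followed the naive list: 0 of 13 were higher and 13 lower (0 and 13 adjusted over the list alone), with adjusted p = 9.8e-12 and 0.0031 with an estimated correlation. Cholesterol synthesis genes were higher in EpiSCs (15 of 17 higher and 0 lower, 16 and 0 adjusted over the list alone, adjusted p = 6.1e-05 and 0.39 with an estimated correlation). In the stress and immediate early list 7 of 12 were higher and 2 lower (8 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.30).

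In that comparison the LIF and STAT3 target list was lower in EpiSCs (2 of 14 higher and 10 lower, 2 and 10 adjusted over the list alone, adjusted p = 0.0085 and 0.70 with an estimated correlation). Tfcp2l1 was at -6.13, Bcl3 at -4.58 and Junb higher at 2.44. The KLF family was called lower as well (1 of 15 higher and 8 lower, 1 and 8 adjusted over the list alone, adjusted p = 0.031 and 0.83 with an estimated correlation): Klf5 at -4.54 ± 0.34, Klf4 at -3.81 ± 0.45 and Klf2 at -3.60 ± 0.74. Epithelial genes were called higher (9 of 14 higher and 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 0.0046 and 0.43 with an estimated correlation, 0.090 in a fit of its libraries alone). Esrp1 was at 4.77 and Cldn4 lower at -4.39. Of 21 listed 2-cell-like genes only Sp110 and Zscan4a, c, e and f were tested. These were lower (0 of 5 higher and 5 lower, 0 and 5 adjusted over the list alone, adjusted p = 3.4e-05 and 0.057 with an estimated correlation). Genes of X inactivation and the Y chromosome were lower too (1 of 5 higher and 4 lower, 1 and 4 adjusted over the list alone, adjusted p = 7.0e-04 and 0.10 with an estimated correlation, 0.053 in a fit of its libraries alone), Xist apart (6.42). Ddx3y, Eif2s3y and Uty were at 0 in EpiSCs, so this comparison cannot separate state from sex of the lines. In all, 7548 of 15454 genes were called, 4154 higher and 3394 lower in EpiSCs, and 3755 with an absolute log2 fold change of at least 1 besides (1826 higher and 1929 lower). The split also turned to 3634 higher and 4276 lower after median-ratio scaling and to 4358 and 4444 with no filter.

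The effect of Klf5 induction was first read on day 2 in LIF, as iKlf5 against iEmpty. Gjb3, a gap junction gene of placenta and epidermis, rose from 0.38 ± 0.0566 to 82.3 ± 1.43 TPM (log2 fold change 5.92 ± 0.19, adjusted p = 2.5e-13). The X-linked homeobox genes Rhox6 and Rhox9, both expressed in placenta, rose to 48.8 ± 2.91 and 31.2 ± 3.45 TPM. Ascl2, a trophoblast transcription factor gene, rose to 46.7 ± 3.34 TPM, Krt7, a keratin of trophoblast and simple epithelia, to 52.7 ± 1.9 and Sox15 to 35.9 ± 1.02. The endoderm factor gene Hnf1b fell from 18.1 ± 0.304 to 0.28 ± 0.0424 TPM and the transcription factor gene Mafb from 33.9 ± 1.43 to 2.06 ± 0.148. Of the naive pluripotency list 14 of 18 rose and 1 fell (14 and 1 adjusted over the list alone), with adjusted p = 2.8e-15 and 4.0e-05 with an estimated correlation. Dppa5a rose by 4.80 ± 0.33 (log2), Dppa3 by 4.33 ± 0.20 and Tfcp2l1 by 3.98 ± 0.26, and the member that fell was Gbx2 (-0.76).

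Trophoblast stem cell genes also rose on day 2 in LIF: 17 of 20 rose and 0 fell (17 and 0 adjusted over the list alone), with adjusted p = 2.0e-13 and 0.034 with an estimated correlation. Among epithelial genes 12 of 14 rose and 0 fell (13 and 0 adjusted over the list alone), with adjusted p = 9.4e-11 and 0.037 with an estimated correlation. The leading members were Tjp3 (2.42), Cldn7 (1.98) and the adhesion gene Epcam (1.95). General pluripotency genes were called upward (5 of 10 up and 2 down, 5 and 2 adjusted over the list alone, adjusted p = 0.021 and 0.39 with an estimated correlation, 0.22 in a fit of its libraries alone). Dppa4 was at 3.06 and Tdgf1 at 3.01, while Lin28a fell by 0.81. Markers of feeder fibroblasts were called downward (0 of 12 up and 8 down, 0 and 8 adjusted over the list alone, adjusted p = 5.4e-05 and 0.38 with an estimated correlation), and Col1a1 fell from 22.6 ± 4.19 to 2.25 ± 0.445 TPM, Tagln by 2.15 and Acta2 by 2.33. Cholesterol synthesis genes were called downward (0 of 17 up and 5 down, 0 and 5 adjusted over the list alone, adjusted p = 2.6e-04 and 0.45 with an estimated correlation), and Cyp51 fell by 0.93. In all, 3303 genes were called, 2067 up and 1236 down, and 1375 with an absolute log2 fold change of at least 1 besides. Quantile normalization turned the split to 1867 up and 2043 down.

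The same induction was read on day 2 with CHIR. Gpx2, a glutathione peroxidase gene of gut epithelium, rose from 2.1 ± 0.495 to 111 ± 0.438 TPM (log2 fold change 5.19 ± 0.16, adjusted p = 1.8e-13). Isx, an intestinal homeobox gene, rose to 31.2 ± 6.39 TPM, the epithelial ETS factor gene Elf3 to 26.6 ± 0.0424, the gelsolin gene Gsn to 45.4 ± 1.17, Emp1 to 41.5 ± 0.389 and Krt7 to 37 ± 1.55. Mt4, a metallothionein gene of squamous epithelium, reached 14.1 ± 0.714 TPM and was listed at 0 in iEmpty. Fgf8 fell from 95.4 ± 2.72 to 34.1 ± 0.134 TPM and the WNT antagonist gene Frzb from 9.36 ± 2.65 to 2.35 ± 0.382. Of the epithelial list 13 of 14 rose and 0 fell (13 and 0 adjusted over the list alone), with adjusted p = 6.4e-16 and 0.010 with an estimated correlation. The leading members were Esrp1 (3.13 ± 0.22) and Epcam (2.81 ± 0.12). Naive pluripotency genes were called upward (10 of 18 up and 0 down, 10 and 0 adjusted over the list alone, adjusted p = 7.8e-07 and 0.0020 with an estimated correlation). Tfcp2l1 was at 2.32, Dppa3 at 2.00 and Nanog at 1.94, all under 7 TPM.

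Trophoblast stem cell genes were called upward as well (11 of 20 up and 0 down, 11 and 0 adjusted over the list alone, adjusted p = 9.5e-07 and 0.16 with an estimated correlation). Tfap2a was at 2.73 and Tead4 at 2.16. In the KLF family 5 of 15 rose and 0 fell (5 and 0 adjusted over the list alone). The list, not tested without the induced Klf5 (7.02), had adjusted p = 0.0088 and 0.75 with an estimated correlation. Klf3 rose by 1.88. Primed pluripotency genes were called downward (1 of 16 up and 4 down, 1 and 5 adjusted over the list alone, adjusted p = 0.036 and 0.82 with an estimated correlation). Fzd2 was at -0.71 and Nodal at -0.59, while Cldn6 rose by 2.66. Glycolysis genes were called downward (1 of 15 up and 3 down, 1 and 3 adjusted over the list alone, adjusted p = 0.0021 and 0.55 with an estimated correlation, 0.17 after quantile normalization). Ldha was at -0.71, while Pdk1 rose by 1.48. Feeder markers were called downward (0 of 12 up and 2 down, 0 and 2 adjusted over the list alone, adjusted p = 0.0020 and 0.57 with an estimated correlation), and the members that fell were Col1a1 and Thy1. In all, 1978 genes were called, 1519 up and 459 down, and 808 with an absolute log2 fold change of at least 1. The count was 984 in a fit of these 4 libraries alone, 1288 without iKlf5_D2_CHIR_LIF replicate 2 and 3347 without both day 5 LIF iKlf5 libraries. The split was 1246 up and 1241 down after quantile normalization and 1514 and 874 after median-ratio scaling.

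On day 5 in LIF, Lgals3 rose from 0.695 ± 0.177 to 119 ± 30.1 TPM (log2 fold change 6.13 ± 0.28, adjusted p = 1.6e-11). The keratin gene Krt19 rose to 328 ± 106 TPM, Krt14 to 34.5 ± 6.54 and Krt5 to 30 ± 1.87, as did Krtdap, a gene of differentiating keratinocytes, to 50.8 ± 9.97. Dppa5a reached 75.9 ± 56.8 TPM and was listed at 0 in iEmpty. Dbx1, a homeobox gene of the developing nervous system, fell from 306 ± 5.52 to 1.36 ± 1.0 TPM, Otp from 95.8 ± 1.99 to 1.34 ± 0.601 and Lhx1 from 27 ± 0.184 to 1.8 ± 1.75. The median of all genes lay at -0.30 (log2), and single genes are given as fitted, not relative to it. Of the epithelial list 14 of 14 rose and 0 fell (14 and 0 adjusted over the list alone), with adjusted p = 3.8e-15 and 0.012 with an estimated correlation. Among naive pluripotency genes 12 of 18 rose and 1 fell (13 and 1 adjusted over the list alone), with adjusted p = 5.4e-10 and 2.6e-04 with an estimated correlation. Nanog rose by 3.09 ± 0.12 to 8.03 ± 0.509 TPM, and Jam2 fell by 0.75. The iEmpty libraries had Nanog at 0.03 and 0.09 TPM and the EpiSC libraries at 83.2 and 91.6, so slower loss than in iEmpty stays possible.

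Differentiated trophoblast genes were called upward on day 5 in LIF (5 of 9 up and 0 down, 5 and 0 adjusted over the list alone, adjusted p = 1.5e-04 and 0.047 with an estimated correlation), and Tpbpa, a spongiotrophoblast gene, rose from 0.295 ± 0.00707 to 14.9 ± 3.29 TPM and Ascl2 to 12.5 ± 2.57. Trophoblast stem cell genes were called upward (11 of 20 up and 2 down, 12 and 3 adjusted over the list alone, adjusted p = 2.2e-08 and 0.099 with an estimated correlation). Rhox9 was at 5.24, while Ddah1 fell by 1.61. General pluripotency genes went both ways (5 of 10 up and 5 down, 5 and 5 adjusted over the list alone, adjusted p = 0.047 and 0.50 with an estimated correlation, 0.21 after quantile normalization), and Pou5f1 rose by 4.22 to 19.9 ± 4.67 TPM while Zfp281 fell by 1.61. Glycolysis genes were called upward (8 of 15 up and 0 down, 8 and 0 adjusted over the list alone, adjusted p = 7.0e-05 and 0.37 with an estimated correlation), and the glucose transporter gene Slc2a1 rose by 1.81. Smaller shifts upward were called in germline genes (4 of 13 up and 0 down, 4 and 0 adjusted over the list alone, adjusted p = 0.0054 and 0.22 with an estimated correlation, 0.33 after quantile normalization), led by Tex19.1 (1.15). The same held for LIF and STAT3 targets (6 of 14 up and 2 down, 6 and 2 adjusted over the list alone, adjusted p = 0.047 and 0.83 with an estimated correlation, 0.078 after median-ratio scaling), led by Bcl3 (2.33). For mitochondrially encoded genes 0 of 13 rose and 6 fell (0 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.85), with the replicates at 6.75% and 14.9% of TPM. In all, 8210 genes were called, 2159 up and 6051 down, and 3036 with an absolute log2 fold change of at least 1. The count was 515 in a fit of these 4 libraries alone (365 up and 150 down) and 1068 with weighted libraries. Without iKlf5_D5_LIF replicate 1 the count was 4586 and without replicate 2 it was 11077, and without iEmpty_D5_LIF replicate 1 it was 5114 and without replicate 2 it was 5306. The split was 3029 up and 3893 down after quantile normalization and 3163 up and 3881 down after median-ratio scaling.

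On day 5 with CHIR, Krtdap reached 60.9 ± 3.33 TPM and was listed at 0 in iEmpty. Emp1 rose from 0.425 ± 0.191 to 75 ± 1.33 TPM (log2 fold change 5.74 ± 0.27, adjusted p = 6.2e-11). The matrix protein gene Tgfbi rose to 99.9 ± 11.3 TPM and Krt19 to 41 ± 2.82. The proneural gene Ascl1 fell from 20.7 ± 8.1 to 4.71 ± 0.0495 TPM, Sox3 from 19.9 ± 4.23 to 5.17 ± 0.00707 and Pou3f3 from 8.6 ± 2.54 to 1.92 ± 0.0283. Of the epithelial list 9 of 14 rose and 0 fell (12 and 0 adjusted over the list alone), with adjusted p = 4.0e-21 and 0.0031 with an estimated correlation. Neural ectoderm genes were called downward (1 of 14 up and 3 down, 1 and 3 adjusted over the list alone, adjusted p = 0.016 and 0.83 with an estimated correlation), though the proneural gene Neurog2 rose by 0.94. Trophoblast stem cell genes were called upward (6 of 20 up and 0 down, 6 and 0 adjusted over the list alone, adjusted p = 2.8e-05 and 0.24 with an estimated correlation). Elf5 was at 2.04 ± 0.19 and Cdx2 at 1.92 ± 0.16, both under 5 TPM. Naive pluripotency genes were called upward with few members past the test (3 of 18 up and 0 down, 3 and 0 adjusted over the list alone, adjusted p = 0.0098 and 0.065 with an estimated correlation, 0.17 after quantile normalization), among them Dppa5a at 2.33 ± 0.622 TPM. Glycolysis genes were called downward (0 of 15 up and 1 down, 0 and 1 adjusted over the list alone, adjusted p = 0.042 and 0.82 with an estimated correlation, 0.38 after quantile normalization), with Tpi1 the member that fell. In all, 1300 genes were called, 862 up and 438 down, 497 with an absolute log2 fold change of at least 1 and 2145 without both day 5 LIF iKlf5 libraries. The count was 775 without iEmpty_D5_CHIR_LIF replicate 1, 836 without iKlf5_D5_CHIR_LIF replicate 1 and 833 without its replicate 2, and quantile normalization gave 839 up and 865 down.

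**Figure D2:**
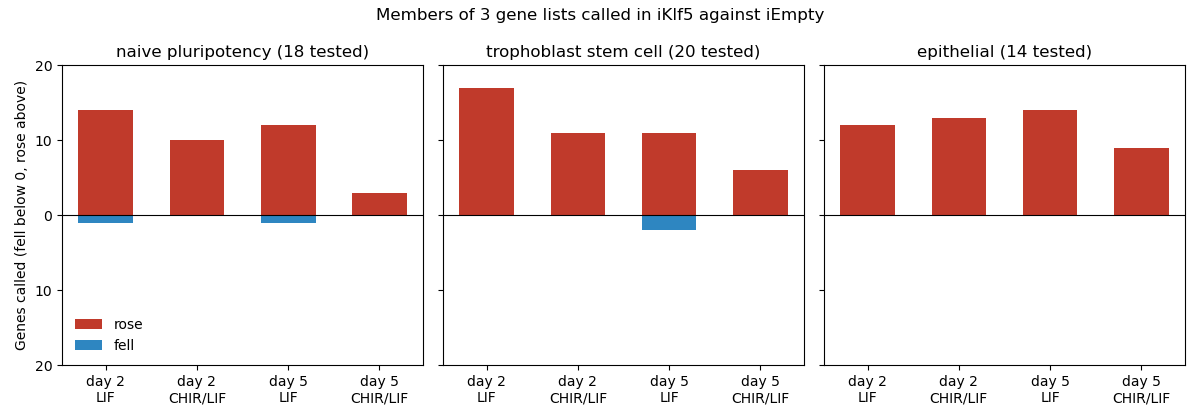
Members of the naive pluripotency (18), trophoblast stem cell (20) and epithelial (14) lists that rose (above 0) or fell (below 0) in iKlf5 against iEmpty, as numbers of genes called in each of the 4 inductions. Between 9 and 14 epithelial genes rose in each induction and none fell, while 14 naive genes rose on day 2 in LIF and 3 on day 5 with CHIR.

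Across the 4 inductions, 394 genes rose and 65 fell in all 4, against 1.58 and 0.407 with independent comparisons. The epithelial list gave 7 of the 394 (Cdh1, Epcam, Krt8, Cldn4, Esrp1, Ocln and St14) and the trophoblast stem cell list 3 (Krt7, Rhox6 and Rhox9). The naive list gave Dppa3 and Fbxo15 and the general pluripotency list Pou5f1 and Dppa4. Between pairs of inductions the log2 fold changes correlated across genes, which are not independent, at r = 0.250 (day 2 with CHIR and day 5 in LIF) to 0.598 (both on day 2). In these 2 pairs 768 and 1014 genes rose in both, against 212 and 203 with independent comparisons, and 204 and 248 fell in both, against 180 and 36.7.

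Whether CHIR changed the response to Klf5 on day 2 was tested as an interaction, the response with CHIR less the response in LIF. In the naive pluripotency list 0 of 18 had a called positive difference and 11 a negative one (0 and 13 adjusted over the list alone), with adjusted p = 2.4e-17 and 3.1e-05 with an estimated correlation and a median of -1.54 (log2). Dppa5a, at 30.2 ± 3.27 TPM in iKlf5 in LIF and 0.165 ± 0.0636 with CHIR, differed by -4.73 ± 0.47 (adjusted p = 2.3e-06), Nr0b1 by -2.88 ± 0.19 and Dppa3 by -2.34 ± 0.28. For trophoblast stem cell genes 1 of 20 had a called positive difference and 8 a negative one (1 and 11 adjusted over the list alone), with adjusted p = 3.2e-09 and 0.080 with an estimated correlation. Rhox9 differed by -3.69 ± 0.31, Rhox6 by -3.46 ± 0.33 and Bmp4, which encodes a BMP ligand, by -3.35 ± 0.34. Isx, at 31.2 ± 6.39 TPM in iKlf5 with CHIR and 0.71 ± 0.24 in LIF, differed by 3.78 ± 0.15, and Mafb by 3.30 ± 0.19. General pluripotency genes were called downward (1 of 10 positive and 4 negative, 1 and 5 adjusted over the list alone, adjusted p = 0.0020 and 0.22 with an estimated correlation). Tdgf1 was at -2.90 and Pou5f1 the other way at 0.82. Primitive streak and mesoderm genes were split (3 of 14 positive and 4 negative, 3 and 5 adjusted over the list alone, adjusted p = 0.030 and 0.46 with an estimated correlation, 0.12 in a fit of its libraries alone). Fgf8 was at -3.14 and Mixl1 at 1.55. Cholesterol synthesis genes were called upward on 3 members (3 of 17 positive and 0 negative, 3 and 0 adjusted over the list alone, adjusted p = 0.0022 and 0.61 with an estimated correlation). Klf5 itself differed by 1.97 ± 0.48 (adjusted p = 0.014), with iEmpty at 26.2 ± 4.67 TPM in LIF and 6.51 ± 2.45 with CHIR. In all, 1261 genes were called, 683 positive and 578 negative, 727 with an absolute difference of at least 1 and 2233 without both day 5 LIF iKlf5 libraries. The split turned to 452 and 484 without iEmpty_D2_CHIR_LIF replicate 1 and to 471 and 503 without iKlf5_D2_LIF replicate 2.

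On day 5 the interaction with CHIR again set naive genes apart: 0 of 18 had a called positive difference and 10 a negative one (1 and 12 adjusted over the list alone), with adjusted p = 3.7e-12 and 1.1e-04 with an estimated correlation. Dppa5a, at 75.9 ± 56.8 TPM in iKlf5 in LIF and 2.33 ± 0.622 with CHIR, differed by -4.31 ± 0.47, Nanog by -2.76 ± 0.17 and Pou5f1 by -2.91 ± 0.24. In the differentiated trophoblast list 0 of 9 had a called positive difference and 3 a negative one (0 and 3 adjusted over the list alone), with adjusted p = 9.3e-05 and 0.044 with an estimated correlation. Tpbpa differed by -3.58 ± 0.15. Rhox9 differed by -4.36 ± 0.31, and its list of trophoblast stem cell genes was called downward (1 of 20 positive and 6 negative, 2 and 7 adjusted over the list alone, adjusted p = 1.5e-04 and 0.33 with an estimated correlation). Dbx1 differed by 5.92 ± 0.29 and Otp by 4.92 ± 0.17, and in iEmpty with CHIR they were at 2.17 ± 1.04 and 1.07 ± 0.262 TPM. Glycolysis genes had negative calls (0 of 15 positive and 7 negative, 0 and 10 adjusted over the list alone, adjusted p = 5.6e-09 and 0.13 with an estimated correlation), with Slc2a1 at -1.59. General pluripotency genes, with Pou5f1 lowest, were called downward (2 of 10 positive and 4 negative, 2 and 5 adjusted over the list alone, adjusted p = 0.0034 and 0.24 with an estimated correlation). Epithelial genes were called downward (1 of 14 positive and 3 negative, 1 and 5 adjusted over the list alone, adjusted p = 0.030 and 0.63 with an estimated correlation, 0.28 with a pseudocount of 0.1 in the other direction), with the epithelial factor gene Ovol2 at -1.73. So were LIF and STAT3 targets, with Ier3 at -1.91 (0 of 14 positive and 3 negative, 0 and 5 adjusted over the list alone, adjusted p = 0.012 and 0.74 with an estimated correlation). Germline genes, with Tex19.1 at -1.10, were called downward (0 of 13 positive and 2 negative, 0 and 2 adjusted over the list alone, adjusted p = 0.0022 and 0.16 with an estimated correlation, 0.21 after quantile normalization). The median of all genes lay at 0.27, with 29.7% ribosomal protein TPM in iKlf5_D5_LIF replicate 1. In all, 2066 genes were called, 1314 positive and 752 negative, and 1080 with an absolute difference of at least 1. The count was 622 in a fit of the 8 libraries alone, 392 with weighted libraries and 9437 without iKlf5_D5_LIF replicate 2, and without its replicate 1 the split was 983 positive and 1035 negative. The count was 1331 without iEmpty_D5_LIF replicate 2 and 1331 without iKlf5_D5_CHIR_LIF replicate 1, and the split was 1171 positive and 1149 negative after quantile normalization and 1163 and 1026 after median-ratio scaling.

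The change of the Klf5 response between day 2 and day 5 was tested in LIF as an interaction, the day 5 response less the day 2 response. Krt19 rose on day 5 and not on day 2 (adjusted p = 0.13), a difference of 4.36 ± 0.37 (adjusted p = 1.1e-07), Krt5 differed by 4.19 ± 0.17 and Lgals3 by 3.80 ± 0.40. Dbx1 differed by -6.93 ± 0.29 and Otp by -5.41 ± 0.17. In the epithelial list 5 of 14 had a called positive difference and 2 a negative one (6 and 2 adjusted over the list alone), with adjusted p = 0.0019 and 0.38 with an estimated correlation. Naive pluripotency genes had more negative calls than positive ones (1 of 18 positive and 11 negative, 3 and 11 adjusted over the list alone, adjusted p = 0.012 and 0.075 with an estimated correlation, 0.54 with a pseudocount of 0.1). Esrrb was at -2.54, Nr0b1 at -2.70 and Fgf4 the other way at 0.64. Glycolysis genes were called upward (8 of 15 positive and 1 negative, 9 and 1 adjusted over the list alone, adjusted p = 4.9e-07 and 0.21 with an estimated correlation), with Slc2a1 at 1.78. Cholesterol synthesis genes followed (5 of 17 positive and 0 negative, 5 and 0 adjusted over the list alone, adjusted p = 0.013 and 0.75 with an estimated correlation), with Msmo1 at 1.01. LIF and STAT3 targets, with Junb at 2.22, did too (4 of 14 positive and 1 negative, 5 and 2 adjusted over the list alone, adjusted p = 0.025 and 0.80 with an estimated correlation, 0.061 after median-ratio scaling). Feeder markers were called upward (3 of 12 positive and 0 negative, 3 and 0 adjusted over the list alone, adjusted p = 0.0034 and 0.62 with an estimated correlation), with Col1a1 at 2.45. Germline genes were called on few members, with Rpl10l at 0.58 (2 of 13 positive and 1 negative, 1 and 1 adjusted over the list alone, adjusted p = 0.038 and 0.39 with an estimated correlation, 0.67 after quantile normalization). Among p53 targets Cdkn1a stood at 2.16 (1 of 12 positive and 0 negative, 1 and 0 adjusted over the list alone, adjusted p = 0.036 and 0.75 with an estimated correlation). The median of all genes lay at -0.38 (log2), so a list with a median near 0 stood above most genes. In all, 4660 genes were called, 1226 positive and 3434 negative, and 2415 with an absolute difference of at least 1. The count was 997 in a fit of the 8 libraries alone and 821 with weighted libraries, and the split was 1896 and 2016 after quantile normalization and 1846 and 2091 after median-ratio scaling. Without 1 library the count was 10294 (iKlf5_D5_LIF replicate 2), 2584 (iEmpty_D2_LIF replicate 1), 2641 (iKlf5_D2_LIF replicate 1), 2869 (iEmpty_D5_LIF replicate 1) or 2963 (iEmpty_D5_LIF replicate 2).

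With CHIR the same change between days set Gpx2 apart, at 111 ± 0.438 TPM in iKlf5 on day 2 and 1.19 ± 0.0283 on day 5, a difference of -4.11 ± 0.22 (adjusted p = 2.7e-09). Fgfbp1 differed by 4.53 ± 0.36 and Krt19 by 3.84 ± 0.37. In the naive pluripotency list 0 of 18 had a called positive difference and 9 a negative one (1 and 9 adjusted over the list alone), with adjusted p = 7.5e-05 and 0.010 with an estimated correlation. Tfcp2l1 was at -1.62 and Nanog at -1.61. Mesenchymal genes were called upward on 1 member, Tgfbi at 2.17 (1 of 12 positive and 0 negative, 2 and 1 adjusted over the list alone, adjusted p = 0.026 and 0.84 with an estimated correlation). The median of all genes lay at -0.14 (log2). In all, 768 genes were called, 252 positive and 516 negative, 461 with an absolute difference of at least 1 and 1663 without both day 5 LIF iKlf5 libraries. The count was 495 without iKlf5_D2_CHIR_LIF replicate 2 and 496 without iEmpty_D5_CHIR_LIF replicate 1.

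What CHIR changed without added Klf5 was read in the iEmpty groups. On day 2 Cdx2, a homeobox gene of trophoblast and of posterior embryonic tissue, rose from 0.145 ± 0.0354 to 152 ± 9.02 TPM (log2 fold change 7.06 ± 0.16, adjusted p = 2.3e-15). The mesoderm gene T (Brachyury) rose to 303 ± 86.6 and Hoxb9 to 148 ± 36.1. L1td1, an RNA-binding protein gene of pluripotent cells, fell from 92.7 ± 0.205 to 2.02 ± 0.0212 TPM. Among primitive streak and mesoderm genes 10 of 14 rose and 2 fell (10 and 2 adjusted over the list alone), with adjusted p = 3.2e-09 and 0.022 with an estimated correlation. General pluripotency genes fell (0 of 10 up and 8 down, 0 and 9 adjusted over the list alone, adjusted p = 2.1e-07 and 0.034 with an estimated correlation), Utf1 by 4.02 and Pou5f1 by 2.64. WNT targets were called upward (8 of 15 up and 0 down, 8 and 0 adjusted over the list alone, adjusted p = 2.3e-08 and 0.16 with an estimated correlation), and Notum rose by 5.52 and Sp5 by 3.84. Primed pluripotency genes fell (0 of 16 up and 11 down, 0 and 11 adjusted over the list alone, adjusted p = 2.7e-05 and 0.37 with an estimated correlation), and Pou3f1 fell by 3.66. Epithelial genes fell (0 of 14 up and 10 down, 0 and 12 adjusted over the list alone, adjusted p = 1.4e-07 and 0.080 with an estimated correlation), and Epcam fell by 2.32. Cholesterol synthesis genes fell as well (0 of 17 up and 13 down, 0 and 17 adjusted over the list alone, adjusted p = 3.1e-07 and 0.23 with an estimated correlation), and Hmgcs1 fell by 1.35. In the KLF family 0 of 15 rose and 7 fell (0 and 7 adjusted over the list alone), with adjusted p = 0.021 and 0.82 with an estimated correlation. In all, 3121 genes were called, 1164 up and 1957 down, 1384 with an absolute log2 fold change of at least 1, 1441 in a fit of these 4 libraries alone and 5042 without both day 5 LIF iKlf5 libraries. Quantile normalization gave 1850 up and 1932 down.

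On day 5 Hoxb9 rose with CHIR from 0.015 ± 0.0212 to 397 ± 59.6 TPM, Hoxa7 to 87.6 ± 6.21 and Hoxd4 to 94.1 ± 9.6. Dbx1 fell from 306 ± 5.52 to 2.17 ± 1.04 TPM, and Otp changed by -5.55 ± 0.12 (log2). Targets of p53 were called upward (8 of 12 up and 0 down, 8 and 0 adjusted over the list alone, adjusted p = 3.6e-09 and 0.094 with an estimated correlation), led by the cell cycle inhibitor gene Cdkn1a, from 15 ± 2.21 to 151 ± 23.4 TPM. Glycolysis genes rose (11 of 15 up and 0 down, 12 and 0 adjusted over the list alone, adjusted p = 3.1e-10 and 0.094 with an estimated correlation), Slc2a1 by 1.27. WNT targets were called upward (8 of 15 up and 1 down, 9 and 1 adjusted over the list alone, adjusted p = 3.0e-05 and 0.37 with an estimated correlation), and Notum rose by 2.92 and Lgr5 by 2.17, with Sp8 the member that fell. Epithelial genes were called downward (0 of 14 up and 9 down, 0 and 9 adjusted over the list alone, adjusted p = 1.6e-04 and 0.24 with an estimated correlation), and Krt8 fell by 4.07. Neural ectoderm genes were called downward (0 of 14 up and 6 down, 0 and 9 adjusted over the list alone, adjusted p = 0.042 and 0.87 with an estimated correlation, 0.088 with a pseudocount of 0.1), and Tubb3 fell by 1.94. Mesenchymal genes were called upward (5 of 12 up and 3 down, 5 and 3 adjusted over the list alone, adjusted p = 0.034 and 0.86 with an estimated correlation, 0.23 after quantile normalization). In all, 5374 genes were called, 1080 up and 4294 down, around a median of -0.24, and 1883 with an absolute log2 fold change of at least 1. The split was 2638 up and 2543 down after quantile normalization and 2024 up and 2901 down after median-ratio scaling.

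How far the day 5 iKlf5 cells stood from ESCs was read for each medium. In LIF, Esrrb was at 1.81 ± 0.573 TPM against 228 ± 4.49 in ESCs and Zfp42 at 1.89 ± 0.742 against 213 ± 6.98. Igf2, an imprinted growth factor gene, was at 819 ± 26.3 against 0.45 ± 0.0283. Naive pluripotency genes stayed lower than in ESCs (1 of 18 higher and 17 lower, 1 and 17 adjusted over the list alone, adjusted p = 2.2e-11 and 1.4e-04 with an estimated correlation), Dppa3 apart (1.45). General pluripotency genes were lower (0 of 10 higher and 9 lower, 0 and 9 adjusted over the list alone, adjusted p = 3.3e-06 and 0.050 with an estimated correlation). Pou5f1 was at -5.12. Germline genes were lower as well (0 of 13 higher and 12 lower, 0 and 12 adjusted over the list alone, adjusted p = 2.1e-08 and 0.012 with an estimated correlation). Neural ectoderm genes were higher (14 of 14 higher and 0 lower, 14 and 0 adjusted over the list alone, adjusted p = 2.6e-07 and 0.37 with an estimated correlation). Hes5 was at 6.20 and Pax6 at 6.15. Trophoblast stem cell genes were called higher (14 of 20 higher and 4 lower, 14 and 4 adjusted over the list alone, adjusted p = 0.016 and 0.64 with an estimated correlation). Rhox6 was at 6.36 and Eomes lower at -3.02. Targets of p53 were lower (0 of 12 higher and 10 lower, 0 and 10 adjusted over the list alone, adjusted p = 0.0040 and 0.55 with an estimated correlation), with Sesn2 at -2.41. Glycolysis genes were lower as well (0 of 15 higher and 11 lower, 0 and 11 adjusted over the list alone, adjusted p = 0.0093 and 0.65 with an estimated correlation), with Pfkp at -3.51. In all, 9971 genes were called, 5382 higher and 4589 lower, and 5502 with an absolute log2 fold change of at least 1. The count was 3842 in a fit of these 4 libraries alone and 4689 with weighted libraries, and 11 of the 22 lists were called, 3 of them also with an estimated correlation. The direction of the split rested on 1 library, with 4892 higher and 6586 lower without iKlf5_D5_LIF replicate 2 and 6791 and 3630 without replicate 1, and it was 5158 and 5271 after quantile normalization and 5274 and 5345 after median-ratio scaling.

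With CHIR, Nanog was at 0.33 ± 0.0283 TPM against 426 ± 6.73 in ESCs and Pou5f1 at 1.58 ± 0.12 against 719 ± 51.7. The neural genes Zic1 and Pax6 were at 530.2 ± 56.4 and 98.7 ± 9.81 TPM against 0.085 ± 0.00707 and 0.11 ± 0.0283. Naive genes were lower than in ESCs (1 of 18 higher and 17 lower, 1 and 17 adjusted over the list alone, adjusted p = 7.8e-13 and 9.6e-05 with an estimated correlation), Gbx2 apart (0.82). General pluripotency genes were lower (0 of 10 higher and 9 lower, 0 and 9 adjusted over the list alone, adjusted p = 1.2e-06 and 0.044 with an estimated correlation), and so were germline genes (0 of 13 higher and 11 lower, 0 and 11 adjusted over the list alone, adjusted p = 1.5e-08 and 0.012 with an estimated correlation). Neural ectoderm genes were higher (13 of 14 higher and 0 lower, 13 and 0 adjusted over the list alone, adjusted p = 1.7e-06 and 0.39 with an estimated correlation), as were mesenchymal genes (10 of 12 higher and 2 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.031 and 0.86 with an estimated correlation). Zeb2 was at 5.08 and Fn1 lower at -2.93. In all, 9267 genes were called, 4954 higher and 4313 lower, and 5024 with an absolute log2 fold change of at least 1 besides, and 11 of the 22 lists were called, 3 of them also with an estimated correlation. Median-ratio scaling gave 4887 higher and 4983 lower.

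Positions between the reference lines were computed per library, with EpiSC at 0 and ESC at 1 on a naive axis of 7548 genes, and EpiSC at 0 and TSC at 1 on a trophoblast axis of 8451 genes. On the naive axis iKlf5 stood at 0.283 ± 0.00135 (SD, n = 2) on day 2 in LIF, 0.258 ± 0.00240 on day 2 with CHIR, 0.292 ± 0.0314 on day 5 in LIF and 0.222 ± 0.00285 on day 5 with CHIR. The iEmpty groups stood, in the same order, at 0.0942 ± 0.00313, 0.158 ± 0.00943, 0.141 ± 0.000106 and 0.156 ± 0.00619. Neither axis is specific to its state, since TSCs stood at 0.476 on the naive axis and wild-type ESCs at 0.417 on the trophoblast axis. On the trophoblast axis iTSC Epi2-1 No5 stood at 0.906 ± 0.00242 and OC-Epi No2 at 0.903 ± 0.0232. The iKlf5 groups stood there at 0.306 and 0.293 on day 2 in LIF and with CHIR and at 0.349 and 0.244 on day 5, against 0.180, 0.191, 0.223 and 0.169 for iEmpty. No test was run on these positions. Libraries held out of an axis end stood at 0.993 and 0.986 for ESC and at 1.01 and 0.933 for TSC.

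**Figure D3:**
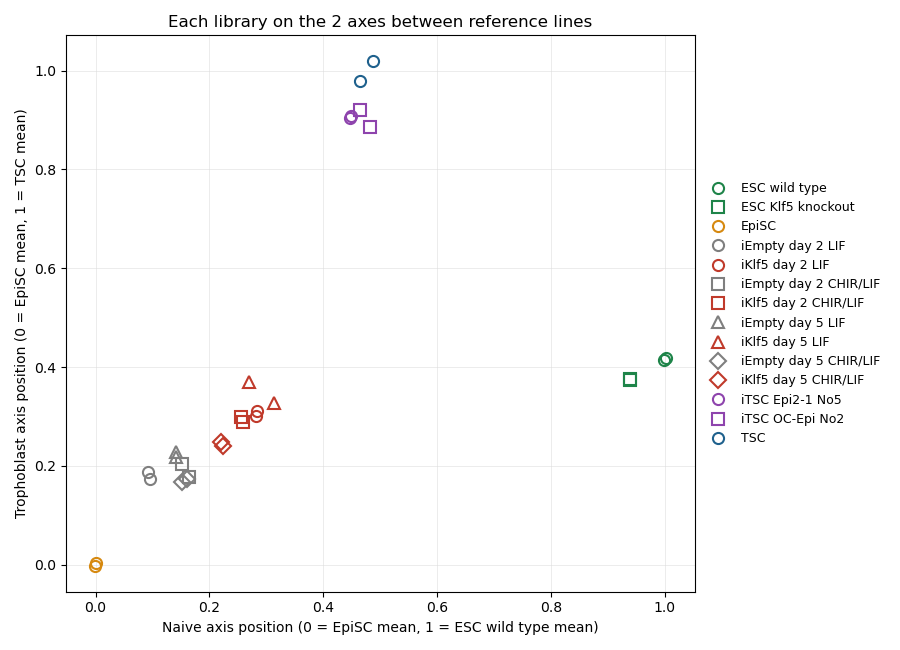
Position of each of the 28 libraries on the naive axis (x, EpiSC at 0 and ESC at 1) and on the trophoblast axis (y, EpiSC at 0 and TSC at 1), both without a unit. The iKlf5 libraries lie right of and above the iEmpty libraries of the same day and medium, and both iTSC lines lie near TSC at about 0.90 on the trophoblast axis.

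Knockout ESCs were read against wild type, where Klf5 loss goes with the chromosome 14 change below. Lefty2 and Lefty1 fell from 79.8 ± 8.05 to 10.1 ± 0.417 TPM (log2 fold change -2.86 ± 0.17, adjusted p = 1.4e-09) and from 21.3 ± 2.75 to 2.92 ± 0.276. Cdx2 rose from 5.68 ± 0.969 to 16.2 ± 0.509 TPM and Hoxa7 from 2.15 ± 0.297 to 6.11 ± 0.735. Klf5 transcripts were still present at 46.3 ± 1.12 TPM against 134 ± 14 (-1.51 ± 0.34, adjusted p = 0.0061). Sp110 and the tested Zscan4 genes of the 2-cell-like list fell (0 of 5 up and 5 down, 0 and 5 adjusted over the list alone, adjusted p = 1.1e-13 and 0.0020 with an estimated correlation), with Zscan4f from 5.91 ± 1.5 to 0.85 ± 0.0141 TPM and every member under 6 TPM. Germline genes were called downward (1 of 13 up and 8 down, 1 and 9 adjusted over the list alone, adjusted p = 1.0e-05 and 0.044 with an estimated correlation, 0.19 in a fit of its libraries alone). Hormad1 was at -1.60 and Tex19.1 rose by 0.79. The Y-linked genes Uty, Eif2s3y and Ddx3y rose by 0.53, 0.47 and 0.47 (3 of 5 up and 0 down, 3 and 0 adjusted over the list alone, adjusted p = 2.1e-05 and 0.044 with an estimated correlation). Epithelial genes were called downward (0 of 14 up and 3 down, 0 and 6 adjusted over the list alone, adjusted p = 0.038 and 0.65 with an estimated correlation, 0.23 after quantile normalization). Krt19 was at -1.92 and Epcam at -1.52. Of the naive pluripotency list 1 of 18 rose and 2 fell (1 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.58), while the knockout stood at 0.939 ± 0.000346 (SD, n = 2) on the naive axis.

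Most genes of chromosome 14 past 33.2 Mb, Klf5 among them, were lower in the knockout. Of 267 genes with at least 5 TPM there, 89.5% had a log2 fold change below -0.5 and the median was -0.94, against 4.21% and -0.01 for the 95 such genes before that point. This stretch held 226 of the 1462 genes called lower. In all, 1620 genes were called, 158 higher and 1462 lower, and 447 with an absolute log2 fold change of at least 1. The count was 2848 in a fit of these 4 libraries alone and 2523 without both day 5 LIF iKlf5 libraries. Without ESC_Klf5_KO replicate 1 the count was 1037, without its replicate 2 it was 959, without ESC_WT replicate 1 it was 977 and without its replicate 2 it was 1067, and quantile normalization gave 552 higher and 989 lower.

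**Figure D4:**
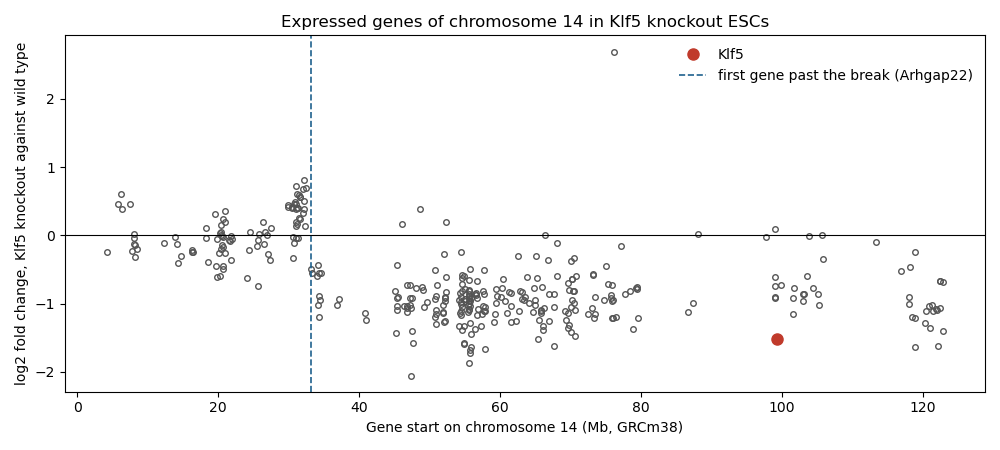
Log2 fold change (knockout over wild-type ESCs) of the 362 genes of chromosome 14 with at least 5 TPM against gene start in Mb, with Klf5 in red and a line at 33.2 Mb. Right of the line the median is -0.94 and left of it -0.01.

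Genes that rose on induction and fell in the knockout were tested by overlap. The comparisons share 1 spread estimate per gene but no library, and genes are not independent, so p-values are inexact. On day 2 in LIF 460 genes rose on induction and fell in the knockout, against 196 by chance (one-sided Fisher exact test, adjusted p = 2.6e-80), and 357 did so on day 2 with CHIR against 144 (adjusted p = 1.3e-66). On day 5 the numbers were 418 against 204 in LIF (adjusted p = 1.2e-53) and 224 against 81.5 with CHIR (adjusted p = 3.6e-48). Genes that did the reverse numbered 25 and 14 on day 2 in LIF and with CHIR against 12.6 and 4.69 (both adjusted p = 0.0015), 42 on day 5 in LIF against 61.9 (adjusted p = 1.0) and 7 with CHIR against 4.48 (adjusted p = 0.22). Overlaps in the same direction passed the test for 32 genes up in both on day 2 in LIF against 21.1 (adjusted p = 0.040) and 61 down in both on day 2 with CHIR against 43.4 (adjusted p = 0.016), and without chromosome 14 for 119 down in both on day 2 in LIF against 96.7 as well (adjusted p = 0.025). Log2 fold changes correlated across genes at r = -0.16, -0.19, -0.13 and -0.14 in that order. After quantile normalization the overlaps were 277 on day 2 in LIF, 205 on day 2 with CHIR and 131 on day 5 with CHIR. Without chromosome 14, left out after seeing the data, they were 411 and 333 on day 2 and 387 and 208 on day 5, in LIF and with CHIR.

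Induced TSC lines were compared with TSCs to show where they differ. In Epi2-1 No5, H19, an imprinted lncRNA of the placenta, was at 13763 ± 50.6 TPM against 32.7 ± 3.03 in TSCs (log2 fold change 8.68 ± 0.38, adjusted p = 2.1e-11), and Krt7 at 109.8 ± 2.28 against 9.45 ± 2.4. The imprinted growth inhibitor genes Cdkn1c, Phlda2 and Grb10 were at 0.81 ± 0.0849, 0.78 ± 0.0283 and 9.23 ± 0.212 TPM against 78.3 ± 8.48, 69.4 ± 6.14 and 334 ± 72. Among trophoblast stem cell genes 5 of 20 were higher and 2 lower (7 and 2 adjusted over the list alone), with adjusted p = 0.0033 and 0.49 with an estimated correlation. Gata2 was at 1.68 and Cdx2 and Bmp4 lower at -0.96 and -1.09. Epithelial genes were called higher (6 of 14 higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.018 and 0.57 with an estimated correlation, 0.067 in a fit of its libraries alone). Glycolysis genes were called higher (4 of 15 higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.034 and 0.80 with an estimated correlation, 0.19 after quantile normalization). Germline genes were called lower (2 of 13 higher and 7 lower, 2 and 8 adjusted over the list alone, adjusted p = 0.0018 and 0.15 with an estimated correlation), with Tex101 at -1.16. General pluripotency genes were called lower too (0 of 10 higher and 4 lower, 0 and 5 adjusted over the list alone, adjusted p = 0.042 and 0.49 with an estimated correlation, 0.11 in a fit of its libraries alone), with Lin28a at -2.56. Klf5 did not pass the test (0.07 ± 0.34, adjusted p = 0.96). In all, 2874 genes were called, 1098 higher and 1776 lower, and 719 with an absolute log2 fold change of at least 1. The count was 4693 without both day 5 LIF iKlf5 libraries, 1725 without iTSC_Epi2-1_No5 replicate 1 and 1681 without its replicate 2. Quantile normalization gave 1680 higher and 1744 lower.

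In OC-Epi No2, H19 was at 5464 ± 453 TPM (log2 fold change 7.34 ± 0.38 against TSCs) and Grb10 at 9.75 ± 3.99. Eif2s3y, a Y-linked gene, was at 46.3 ± 3.62 TPM against 1.4 ± 0.184 in TSCs and Xist at 3.65 ± 1.24 against 63.8 ± 14.3, so this line and the TSC line differed in genes of the sex chromosomes. The list of X inactivation and Y-linked genes was called higher (3 of 5 higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 4.5e-05 and 0.050 with an estimated correlation). Trophoblast stem cell genes were called higher (7 of 20 higher and 2 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.0016 and 0.43 with an estimated correlation). Krt7 was at 3.56, Esx1 at 3.37 and Cdx2 lower at -0.71. Differentiated trophoblast genes were called higher (3 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone, adjusted p = 4.4e-04 and 0.061 with an estimated correlation). Phlda2 was at 2.35 and Ascl2 at 2.10. Germline genes were called lower (0 of 13 higher and 8 lower, 0 and 10 adjusted over the list alone, adjusted p = 1.9e-04 and 0.080 with an estimated correlation), with Ddx4 at -1.31. Primed pluripotency genes were called lower (0 of 16 higher and 6 lower, 0 and 8 adjusted over the list alone, adjusted p = 0.015 and 0.75 with an estimated correlation), with Sox3 at -1.92. Primitive streak genes, T (Brachyury) among them at -2.09, were called lower as well (0 of 14 higher and 5 lower, 1 and 7 adjusted over the list alone, adjusted p = 0.028 and 0.45 with an estimated correlation, 0.16 in a fit of its libraries alone). Mitochondrially encoded genes were called higher (3 of 13 higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.043 and 0.62 with an estimated correlation, 0.41 after quantile normalization). ND2 was at 1.27. In all, 3433 genes were called, 1269 higher and 2164 lower, and 1008 with an absolute log2 fold change of at least 1. The count was 1179 in a fit of these 4 libraries alone and 5212 without both day 5 LIF iKlf5 libraries, and median-ratio scaling gave 1884 higher and 2070 lower. The 2 lines shared 627 genes higher and 1232 lower than TSCs, and their fold changes correlated at 0.727 across genes where simulated lines that share the TSC libraries alone gave 0.50.

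Trophoblast genes were higher in both iTSC lines and in TSCs than in EpiSCs. Line and state are not separated, since OC-Epi No2 had Y-linked RNA (Ddx3y) and EpiSCs none. Elf5 was listed at 0 in EpiSCs and at 413 ± 4.38 TPM in Epi2-1 No5, 468 ± 61.8 in OC-Epi No2 and 408 ± 31.7 in TSCs. Hand1 was higher by 9.79 ± 0.56, 10.46 ± 0.56 and 9.84 ± 0.56 (log2) in that order and Rhox5 by 10.34 ± 0.23, 10.08 ± 0.23 and 10.20 ± 0.23. Pou5f1 was lower, at -9.44 ± 0.17, -9.39 ± 0.17 and -8.36 ± 0.17, and Otx2 at -6.98 ± 0.21, -6.86 ± 0.21 and -6.91 ± 0.21. Of the trophoblast stem cell list 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone) in both lines. Epi2-1 No5 had adjusted p = 1.1e-13 and OC-Epi No2 adjusted p = 9.7e-14, and both 0.034 with an estimated correlation. In TSCs 19 of 20 were higher and 0 lower (19 and 0 adjusted over the list alone), with adjusted p = 2.2e-11 and 0.049 with an estimated correlation. Markers of feeder fibroblasts were higher too, with Col1a1 at 41.4 ± 0.212 TPM in Epi2-1 No5, 73.1 ± 39.1 in OC-Epi No2 and 51.5 ± 11.1 in TSCs against 0.385 ± 0.0919 in EpiSCs. For these markers 10 of 12 were higher and 0 lower (10 and 0 adjusted over the list alone) in Epi2-1 No5 (adjusted p = 3.8e-05 and 0.37 with an estimated correlation), with Mgp listed at 0 in EpiSCs and at 76.2 ± 6.77 TPM.

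Primed pluripotency genes were lower against EpiSCs in Epi2-1 No5 (3 of 16 higher and 12 lower, 3 and 12 adjusted over the list alone, adjusted p = 1.4e-04 and 0.43 with an estimated correlation). They were called lower in OC-Epi No2 (2 of 16 higher and 13 lower, 2 and 13 adjusted over the list alone, adjusted p = 2.1e-05 and 0.37 with an estimated correlation) and in TSCs (2 of 16 higher and 10 lower, 2 and 10 adjusted over the list alone, adjusted p = 5.4e-04 and 0.50 with an estimated correlation) as well, while Sox3 was higher at 2.28, 1.46 and 3.38. Glycolysis genes were lower, with Ldha at -1.60 in Epi2-1 No5 (0 of 15 higher and 11 lower, 0 and 11 adjusted over the list alone, adjusted p = 2.9e-04 and 0.42 with an estimated correlation) and -2.37 in OC-Epi No2 (0 of 15 higher and 14 lower, 0 and 14 adjusted over the list alone, adjusted p = 2.5e-06 and 0.24 with an estimated correlation). Among extraembryonic endoderm genes 12 of 15 were higher and 0 lower (12 and 0 adjusted over the list alone) in Epi2-1 No5 (adjusted p = 1.6e-04 and 0.40 with an estimated correlation), led by the basement membrane genes Col4a2 (5.26) and Col4a1 (4.19), which that lineage shares with others. Germline genes were higher in TSCs (11 of 13 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 3.4e-05 and 0.051 with an estimated correlation). Epithelial genes were higher in TSCs as well (10 of 14 higher and 1 lower, 10 and 1 adjusted over the list alone, adjusted p = 0.0021 and 0.38 with an estimated correlation), with Cldn4 at 6.69. Differentiated trophoblast genes were higher in OC-Epi No2 (7 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone, adjusted p = 0.0045 and 0.14 with an estimated correlation). In all, 8444 genes were called for Epi2-1 No5 (4355 higher, 4089 lower), 8735 for OC-Epi No2 (4382 higher, 4353 lower) and 8451 for TSCs (4697 higher, 3754 lower), and 4287, 4444 and 4363 with an absolute log2 fold change of at least 1 besides. For Epi2-1 No5 7 of the 22 lists were called, 1 of them also with an estimated correlation, for OC-Epi No2 10 and 1, and for TSCs 8 and 1. Quantile normalization gave 4104 higher and 5152 lower for Epi2-1 No5, 4200 and 5291 for OC-Epi No2 and 4149 and 5131 for TSCs. The split of OC-Epi No2 also turned in 4 other alternatives, as in a fit of these libraries alone (4731 and 4935).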

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

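The tests on chromosome 14, on chromosomes 11 and 6, on gene span and on a wrong label were chosen only after the results they weigh were seen, and the test on cell states before.

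The response to Klf5 induction differed between media by the interaction test at 1261 genes on day 2 and 2066 on day 5. Between days it differed at 4660 genes in LIF and 768 with CHIR. The naive pluripotency list had a median difference between media of -1.54 (log2) on day 2 and -0.94 on day 5, and between days with CHIR of -0.83. The differentiated trophoblast list had a median difference between media of -0.84 on day 5.

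In knockout ESCs the genes of chromosome 14 from Arhgap22 (33.2 Mb) on were lower: 89.5% of the 267 expressed ones lay below -0.5 (log2), against 4.21% of the 95 before that point, with a median of -0.93 and -0.96 in the 2 libraries. Scaling was argued against by medians past that point of -0.76 and -0.85 after 2 other scalings. So was KLF5 itself keeping these genes expressed. On induction their median lay at most 0.0585 (log2) above that of other autosomes, and -0.0221 from it on day 2 in LIF. Loss of 1 copy of this stretch, which holds Klf5, had the values it needs and may be the source of the 226 lower calls there. Loss with the knockout or in culture stays open, and no other biological explanation was tested. Without chromosome 14, 1349 genes were called, and there and in the overlaps Klf5 loss and this stretch cannot be told apart.

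Both iTSC lines were lower than TSCs on chromosome 11 by a median of -0.38 (Epi2-1 No5) and -0.36 (OC-Epi No2) relative to other autosomes, but not alike along it: from 30 to 60 Mb the medians per 10 Mb, not set against other autosomes, were -0.04, -0.07 and -0.05 in OC-Epi No2 and -0.29, -0.41 and -0.43 in Epi2-1 No5, and from 70 to 90 Mb -0.50 and -0.65 against -0.44 and -0.50. More copies of chromosome 11 and part of 6 in the TSC line cannot be told apart from line differences in expression, since chromosome 11 was higher in TSCs by 0.530 against EpiSCs and 0.471 against ESCs, as extra copies need, but in the iTSC lines by 0.109 and 0.182 against EpiSCs, where they need a value within 0.1. From 76 Mb of chromosome 6 on, a boundary chosen after seeing the data, TSCs were higher by 0.490 against EpiSCs and the iTSC lines by 0.00462 and -0.0518. A different share of feeder fibroblasts cannot be told apart either, since the feeder markers had a median of -0.31 in Epi2-1 No5 and 0.32 in OC-Epi No2 against TSCs and the list was called in neither line, while leaving these markers out (-0.385 and -0.362), or called genes as well (-0.381 and -0.348), decides nothing. Different line origins stay open as untested.

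The replicates of day 5 iKlf5 in LIF had 4384 genes with a known span over 2-fold apart. A trend with gene span, as a loss of long transcripts would give, was argued against as the whole cause, since 2292 stayed over 2-fold apart once the trend was removed (rho = -0.49), against 325 in the next group, and a wrong label on replicate 1 was argued against by its correlation of 0.933 with replicate 2, above the 0.92 with a library of any other group. A different mix of cell states in replicate 1 cannot be told apart from other causes, since 2 lists had a median difference over 0.5 after the trend was removed (neural ectoderm -0.80 and primed pluripotency -0.50), where a different mix needs 3 and its absence 0 over 0.2. The difference between the replicates correlated across genes at 0.778 with that of iEmpty day 2 with CHIR, 0.622 with iEmpty day 2 in LIF and 0.415 with iKlf5 day 2 with CHIR, groups that share the span trend (rho = -0.44, -0.42 and -0.29). In each, ribosomal protein genes also took more of replicate 1 than of replicate 2 (20.7% and 15.4% in the first). Mitochondrial genes took less (12.4% and 15.0%). The same held in wild-type ESCs, EpiSCs and TSCs, without that trend. A shared effect of RNA quality or library making and a biological difference between the cultures stay open, both untested.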

How the results depend on the processing

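The tests without chromosomes 14, 6 and 11, without both day 5 LIF iKlf5 libraries, with weighted libraries and with a crossed replicate block were chosen only after the results were seen. Of the changes of setting to the counts of called genes, leaving out a library apart, 106 chosen before the data were examined stayed within 1.5 times and 27 did not, and of those chosen later 11 stayed and 12 did not. For the overlaps with the knockout 37 of the first stayed and 3 did not, and all 8 of the later ones stayed. For the called lists 646 changes kept the call and its direction, 157 lost the call and 1 turned, the epithelial list in the Klf5 by CHIR interaction of day 5 (adjusted p = 0.281 with a pseudocount of 0.1). For the named genes 1403 changes kept the call and 37 lost it, 24 of these in a fit of the comparison's libraries alone, while of those chosen later 285 kept it and 11 lost it, all 11 with weighted libraries, and with 1 library left out 1099 kept it and 37 lost it. Calls were lost for Klf5, Uty, Eif2s3y and Ddx3y (knockout), Frzb, Fzd2, Klf3, Ldha and Pdk1 (day 2 CHIR), Ascl2, Bcl3, Ddah1, Jam2, Lhx1 and Zfp281 (day 5 LIF), Pou5f1 and Klf5 (CHIR interaction, day 2), Ier3, Slc2a1 and Tex19.1 (day 5), Fgf4, Msmo1, Rpl10l and Slc2a1 (day interaction, LIF), Nanog and Tfcp2l1 (CHIR), Dppa3 (day 5 LIF against ESCs), Gata2 and Cdx2 (Epi2-1 No5 against TSCs) and Ascl2, Cdx2, ND2, Phlda2 and Sox3 (OC-Epi No2). The cause of these moves was not tested, except that a minimum fold change, fewer libraries and another spread act by construction. With unknown depth, the counting error at low TPM is not known.

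With an absolute log2 fold change of at least 1 the counts were 447 for the knockout, 1375, 808, 3036 and 497 for the inductions (day 2 LIF, day 2 CHIR, day 5 LIF, day 5 CHIR), 727 and 1080 for the CHIR interactions (day 2, day 5), 2415 and 461 for the day interactions (LIF, CHIR), 1384 and 1883 for CHIR in iEmpty, 3755 for EpiSCs, 5502 and 5024 for day 5 iKlf5 against ESCs (LIF, CHIR), 719 and 1008 for Epi2-1 No5 and OC-Epi No2 against TSCs, 4287 and 4444 against EpiSCs, and 4363 for TSCs against EpiSCs. In a fit with only the libraries of the comparison they were 2848 for the knockout, 984 for day 2 CHIR, 515 for day 5 LIF, 622 for the day 5 CHIR interaction, 997 for the day interaction in LIF, 1441 for CHIR in iEmpty on day 2, 3842 for day 5 LIF against ESCs and 1179 for OC-Epi No2 against TSCs. Without both day 5 LIF iKlf5 libraries they were 2523 for the knockout, 3347 for day 2 CHIR, 2145 for day 5 CHIR, 2233 for the day 2 CHIR interaction, 1663 for the day interaction with CHIR, 5042 for CHIR in iEmpty on day 2, and 4693 and 5212 for Epi2-1 No5 and OC-Epi No2 against TSCs. With weighted libraries they were 1068 for day 5 LIF, 392 for the day 5 CHIR interaction, 821 for the day interaction in LIF and 4689 for day 5 LIF against ESCs. Without chromosomes 6 and 11 Epi2-1 No5 and OC-Epi No2 against TSCs gave 2239 and 2691, and for day 2 LIF a fit of its 4 libraries alone gave 3034 without a block, 1495 with a block by replicate number and 3151 with the crossed block. Quantile normalization gave overlaps with the knockout of 277, 205 and 131 (day 2 LIF, day 2 CHIR, day 5 CHIR), and the estimated correlation 30 of 134 lists.

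Naive positions (day 2 CHIR, day 2 LIF, day 5 CHIR) were 0.283, 0.310 and 0.238 with a pseudocount of 0.1, 0.233, 0.263 and 0.182 after quantile normalization (0.242 for day 5 LIF) and 0.253, 0.282 and 0.208 after median-ratio scaling. The trophoblast position of Epi2-1 No5 was 0.903 with no filter and 0.913 after median-ratio scaling.

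Leaving out 1 library, where the lone sample of a group is assumed to vary like the other groups, gave 959–1067 for the knockout, 2330–2594, 1288–1745, 4586–11077 and 775–951 for the inductions, 873–1098 and 1331–9437 for the CHIR interactions, 2584–10294 and 495–668 for the day interactions, 2159–2716 and 3701–4149 for CHIR in iEmpty, 6190–6278 for EpiSCs, 8536–11478 and 7949–8063 for day 5 iKlf5 against ESCs, 1681–2443 and 2496–3037 for Epi2-1 No5 and OC-Epi No2 against TSCs, 7074–7165 and 7386–7803 against EpiSCs, and 7171–7608 for TSCs against EpiSCs, in the order above. Naive positions were 0.282–0.295, 0.254–0.270, 0.270–0.314 and 0.220–0.232 in the order of the inductions, and trophoblast positions 0.873–0.913 for Epi2-1 No5 and 0.874–0.92 for OC-Epi No2. The highest counts for day 5 LIF and for both interactions that use it came without iKlf5_D5_LIF replicate 2.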

Other observations

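The test on imprinted genes was chosen only after the result was seen.

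Of 38 imprinted genes, 15.8% (H19, Grb10, Igf2r, Peg12, Zrsr1 and Airn) were called over 2-fold apart from TSCs alike in both iTSC lines. Of 10097 expressed genes 2.51% were. The 38 include Calcr, at 0.005 TPM in TSCs and both lines, so the shares may not compare. H19 and Grb10 prompted the test, so no p-value is given. A shift of imprinted genes as a group cannot be told apart from changes at single genes. It needs 50% of them, and its absence under 2 times the share of all genes. Cdkn1c and Phlda2, imprinted as well, were lower than in TSCs in Epi2-1 No5 (-5.45 and -5.30) and higher in OC-Epi No2 (1.26 and 2.35).

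Xist stood at 132 TPM in EpiSCs, 63.8 in TSCs, 109 in iTSC Epi2-1 No5, 3.65 in iTSC OC-Epi No2 and 0.545 in ESCs. The Y-linked Ddx3y stood at 16.5 TPM in ESCs and 16.5 in OC-Epi No2 and was listed at 0 in EpiSCs. Hprt stood at 0.3 TPM in wild-type ESCs, 0.435 in knockout ESCs and 153 in EpiSCs.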
